A study of Homo sapiens with 7 samples.

How the data were processed

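RNA sequencing data of cells labelled as Kasumi-1 were analysed: 2 libraries labelled parental, 3 of MR1 and 2 of MR2, MR1 and MR2 being labelled as resistant to AMG-176. Per the labels' protocols, poly(A) RNA was taken from total RNA and libraries were made with a directional kit. Per the submitters' processing notes, STAR 2.5.0c, Picard 2.6.0 and edgeR 3.14.0 were used with the hg19 build; which step each served, the program that counted reads, its strand setting and the gene annotation are not given in the sources used here. Because strand use in counting is not stated, genes with an antisense or overlapping partner are uncertain, as are genes with near-identical copies, such as the HLA genes. Genes are given by the symbols in the deposited tables, and no coordinates are printed because the reference genome at hand was of another build.

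The authors deposited a table of raw read counts per gene symbol and a table of FPKM values, each with 1 column per library. The counts held 59611 genes, of which 32440 had a count in some library. No row was without a gene name, and all columns were used. The deposited FPKM equalled the count divided by the count total and by 1 length per gene: over 5724 well-counted genes the implied length varied by at most 0.0647% between libraries, so FPKM carried no further scaling. The list of 13 mitochondrially encoded transcripts had 0 rows and was not analysed here.

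Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (17550 genes, holding at least 99.939% of the counts of each library), scaled by TMM, and fitted by the quasi-likelihood method with 1 coefficient per group over all 7 libraries, which leaves 4 residual degrees of freedom. Contrasts were MR1 against parental, MR2 against parental, the mean of MR1 and MR2 against parental, and MR1 against MR2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. CPM values are TMM-scaled unless the text says CPM of the library total. A standard error is the log2 difference divided by the root of the quasi-likelihood F. Folds against an arm with no count are lower bounds from a floor of 3 counts over the group; for 1 to 3 counts the ratio has an exact 95% binomial interval. Intervals and floors cover counting error only, since the reads carried no molecular identifiers in the sources used here.

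Count totals ran from 38147759 to 67082599, so 1 count was worth at most 0.0262 CPM in any library; precision was set by the spread between libraries (common coefficient of variation 0.206) rather than by depth for all but low genes. Replicates were compared before averaging: counts of any pair within a group differed by 21.58 to 172.7 times the sampling noise (chi-square over its degrees of freedom), so none was the same library sequenced again; separate libraries of 1 culture are not excluded. The group labelled parental shares 1 replicate number with each line, and MR1 and MR2 share none. The correlation of deviations from the group means was 0.013 for the pair numbered 2 and 0.185 for the pair numbered 3.

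A total of 40 lists of genes were fixed before the data were examined, together with the groups, the tests, the other settings to be tried and the rule for named genes. Lists with at least 3 tested members (39) were tested with limma 3.58.1 by camera on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over the lists, and beside it by camera with an estimated correlation and by fry. The rule named every tested BCL2 family gene; the 12 called genes of mitophagy and mitochondrial dynamics with the smallest adjusted p, with 9 such genes whatever their result, of which 1 is not reported here; the 12 highest and 12 lowest genes of the mean contrast (called in both lines in the same direction, with no overlap of libraries and at least 5 CPM in the higher group); the 10 highest and 10 lowest between MR1 and MR2, of which there were 0; the 6 highest and 6 lowest in each line; and up to 4 called members of each called list. Genes named outside the rule are said to be so where they appear. Clone names, antisense and most other noncoding symbols, and transcripts tied to one sex, were passed over in naming the highest and lowest genes.

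The fits were tested on simulated counts drawn from the real means, totals and dispersions of the 17550 genes, with 200 changed genes per comparison. For the mean of MR1 and MR2 against parental, 34.8% of 2-fold and 85.7% of 4-fold changes were recovered with 2 false calls. For MR1 against parental the shares were 27.7% and 81.5% with 8 false calls, for MR2 against parental 20.6% and 82.5% with 11, and for MR1 against MR2 31% and 72.6% with 5. These simulations changed 200 of 17550 genes, while most tested genes were called in the real contrasts against parental. Their adjusted threshold was therefore stricter, and their shares and false calls do not carry over to those contrasts. Of 40 simulated lists, the 5 shifted by 0.5 log2 were called and 0 others. These lists were random, no other genes were changed, and each gene was drawn independently. They therefore do not test camera on lists whose genes move together. In the real data the estimated correlation was 0.857 for ribosomal protein genes and 0.821 for replication genes.

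The other settings fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of at least 1 CPM in every library of a group, limma on log2 of the deposited FPKM plus 0.1 (at least 0.5 FPKM in 2 libraries) or plus 1, the former also without a filter, a test against a fold of 1.5, leaving out each library in turn, only the groups compared, a replicate block, other set tests and a prior count of 0.5. Thinning of every library to the smallest total and removal of a smooth trend with gene length were chosen after seeing the data.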

Results

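Poly(A) RNA was sequenced from cells that the labels give as Kasumi-1, a human acute myeloid leukaemia line known for a chromosomal translocation that fuses RUNX1 to RUNX1T1. The series asked which transcripts go with resistance to AMG-176, an inhibitor of the anti-apoptotic protein MCL1. MR1 and MR2 are cells labelled as resistant, grown in doses raised from 30 nM to 1.6 uM over 8 weeks, and the labels give the other cells as parental and untreated. There were 2 libraries labelled parental, 3 of MR1 and 2 of MR2. Gene counts summed to 43220782 and 38147759 in the libraries labelled parental. They summed to 47277711, 67082599 and 38894380 in MR1 replicates 3, 4 and 6, and to 42975926 and 52470389 in MR2 replicates 2 and 5. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. They also do not say whether drug was present at harvest.

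The libraries labelled parental had next to none of the transcript that marks this line. RUNX1T1, which Kasumi-1 transcribes from its fusion gene, had 3 counts in each library labelled parental, or 0.0694 and 0.0786 CPM of the library total. In the 5 resistant libraries RUNX1T1 had 6487 to 8259 counts, or 118 to 171 CPM. POU4F1, a transcription factor gene known to be expressed in leukaemias with this fusion, was at 1.39 and 0.996 CPM in the libraries labelled parental and at 33.6 to 57.1 CPM in the resistant ones. Some genes of blood cell identity, chosen after their values were seen, also had levels that did not overlap between these libraries and the resistant ones. After TMM scaling, the stem cell factor receptor gene KIT was at 2.13 and 2.02 CPM in the libraries labelled parental and at 1860 to 2507 CPM in the resistant libraries. CD34, a surface marker of blood progenitors, was at 0.332 and 0.169 CPM against 422 to 612 CPM. In the other direction, HOXA9 was at 95.8 and 66.9 CPM in the libraries labelled parental and at 0.736 to 1.91 CPM in the resistant libraries. LYZ, which encodes lysozyme, was at 413 and 1002 CPM against 1.49 to 2.00 CPM, and the filament gene VIM was at 1275 and 1770 CPM against 0.0570 to 0.486 CPM. MEIS1, a partner of HOXA9, was at 66.0 and 55.1 CPM and had no count in any resistant library. The label "parental" is therefore used below only as a name for these 2 libraries.

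**Figure D1:**
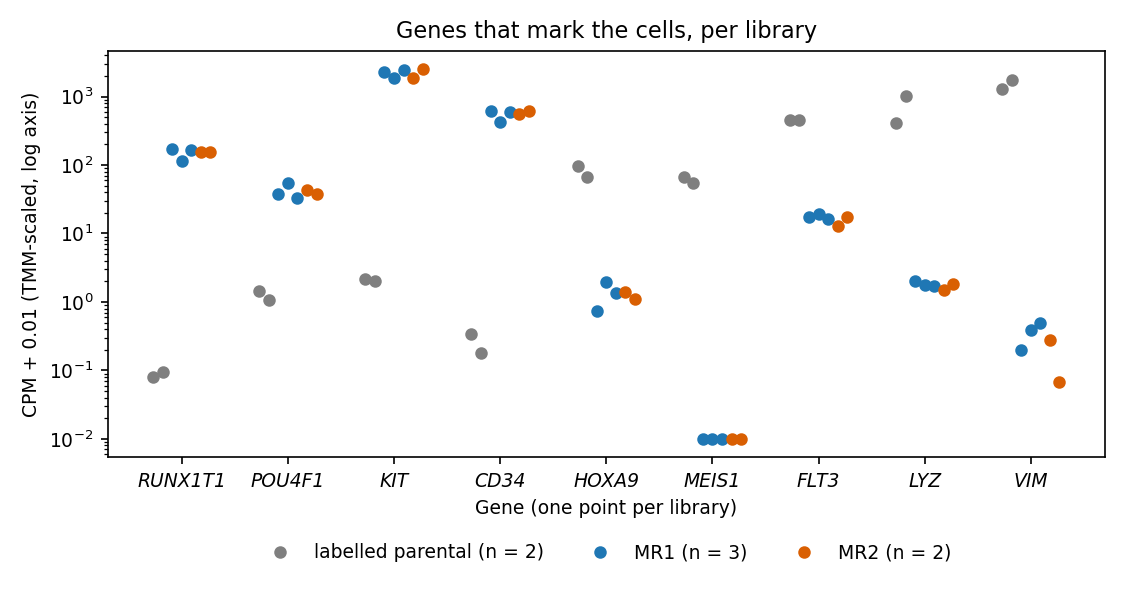
TMM-scaled CPM plus 0.01 (log axis) of 9 genes, with 1 point per library, for the 2 libraries labelled parental, 3 of MR1 and 2 of MR2. The groups do not overlap for any gene shown: RUNX1T1, POU4F1, KIT and CD34 are higher in all 5 resistant libraries, and HOXA9, MEIS1, FLT3, LYZ and VIM are higher in both libraries labelled parental.

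The comparison of the mean of MR1 and MR2 with the libraries labelled parental called most tested genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10636 of 17550 genes (60.6%) differed, 5493 higher and 5143 lower in the resistant libraries. Of these, 7281 differed by over 2-fold and 2574 by over 16-fold. Counted without a test, 163 genes were above 10 CPM in both libraries labelled parental and below 0.1 CPM in all 5 resistant ones, and 194 genes showed the reverse. The first principal component held 93.1% of the variance and separated the libraries labelled parental from the rest. Across genes of at least 10 CPM, Pearson's r between a library labelled parental and a resistant one was 0.3985 to 0.4214, against 0.9596 to 0.9921 within groups; genes are not independent replicates. All directions below are relative to libraries with 3 counts of RUNX1T1 each.

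MCL1 itself, the drug's target, was at 219 ± 12.9 CPM (SD, n = 5) in the resistant libraries and 281 ± 30 CPM (SD, n = 2) in the libraries labelled parental. The log2 difference was -0.37 ± 0.13 (SE; edgeR adjusted p = 0.0314), lower in 5 of 5 resistant libraries. The call ended in 7 of 20 alternatives, among them leaving out parental replicate 3 (adjusted p = 0.241), MR2 replicate 2 (0.0698) or MR2 replicate 5 (0.098), over a range of 0.0169 to 0.971. Of the 5 tested anti-apoptotic BCL2 family genes, 1 was higher and 2 were lower in the resistant libraries, with the same counts adjusted over the list alone. BCL2L1, which encodes BCL-XL, was 4.02-fold higher (log2 2.01 ± 0.16, edgeR adjusted p = 6.84e-06), at 88.0 ± 8.44 CPM (SD, n = 5) against 22.0 ± 2.69 CPM (SD, n = 2). BCL2A1 was 8.12-fold lower (log2 -3.02 ± 0.36, edgeR adjusted p = 1e-04). BCL2 had a log2 difference of -0.38 ± 0.16 that missed the threshold (edgeR adjusted p = 0.0638). It passed in 5 of 20 alternatives, among them leaving out MR1 replicate 4 (0.0259) or MR1 replicate 6 (0.0421), over a range of 0.00387 to 0.896 in its alternatives. BCL2L2, at -0.38 ± 0.17 (0.0865), passed in 2 of 20, among them leaving out MR1 replicate 4 (0.00539), over a range of 0.00539 to 0.854.

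All 11 tested pro-apoptotic BCL2 family genes were called, 3 higher and 8 lower in the resistant libraries, as they were adjusted over the list alone. The effector gene BAX was 2.49-fold lower (log2 -1.31 ± 0.11, edgeR adjusted p = 1.12e-05) and BAK1 1.73-fold lower (log2 -0.79 ± 0.13, 0.000767). Among the BH3-only genes, whose products trigger the effectors, BBC3 (PUMA) was 9.36-fold lower, BMF 5.3-fold, BIK 2.18-fold, BID 1.8-fold and BCL2L11 (BIM) 1.36-fold lower. HRK was 38.5-fold lower, at 2.11 CPM against 0.0509 CPM. PMAIP1, which encodes the MCL1-binding protein NOXA, was 2.31-fold higher (log2 1.21 ± 0.19, edgeR adjusted p = 0.000485) and BAD was 1.62-fold higher. BOK had no count in the libraries labelled parental and 4.27 CPM in the resistant ones, which makes it at least 113-fold higher against a floor of 3 counts over the group. The BCL2L11 call ended without parental replicate 2 (edgeR adjusted p = 0.0851, range over its alternatives 0.00313 to 0.856). Against a fold of 1.5, BCL2L11 (0.856), BAK1 (0.0562, highest of a range from 5.16e-06) and BAD (0.165, highest of a range from 0.000217) were no longer called. As a set neither BCL2 list was called by camera (adjusted p = 0.517 for the anti-apoptotic and 0.216 for the pro-apoptotic genes). Fry, which does not compare a list with the other genes, called the pro-apoptotic list (adjusted p = 0.00618) and not the anti-apoptotic one (0.823).

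Of 36 tested mitophagy genes, 7 were higher, 11 lower and 18 not called, with the same counts adjusted over the list alone. Camera did not call the set (adjusted p = 0.356), and fry did (adjusted p = 0.00499). Of all tested genes 60.6% were called, and fry called 26 of the 39 lists. Neither the counts nor the fry call therefore marks a change particular to mitophagy genes. SQSTM1 (p62) was 3.53-fold lower (log2 -1.82 ± 0.15, edgeR adjusted p = 9.6e-06), OPTN, another adaptor, was 42.7-fold lower (log2 -5.41 ± 0.43, 7.71e-06), and the inner-membrane receptor gene PHB2 was 2.4-fold lower (log2 -1.27 ± 0.12, 2.07e-05). VDAC3 was 2.56-fold lower, and SRC, a kinase gene, was 108-fold lower. NIPSNAP1 was 3.68-fold higher (log2 1.88 ± 0.13, edgeR adjusted p = 2.76e-06). PINK1, a kinase gene that starts one route of mitophagy, differed by 0.24 ± 0.24 on the log2 scale (edgeR adjusted p = 0.418). BNIP3 differed by 0.15 ± 0.39 (0.759), with 249 CPM in MR1 replicate 4 and 83.8 to 124 CPM in the other 4 resistant libraries. Its sign turned without parental replicate 2 (-0.23) or MR1 replicate 4 (-0.12). BNIP3L was at -0.49 ± 0.26 (edgeR adjusted p = 0.129) and passed in 3 of 20 alternatives, among them leaving out MR1 replicate 4 (0.0186), over a range of 0.0081 to 0.8. MARCHF5 was at -0.10 ± 0.14 (0.549).

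Genes of mitochondrial fusion, fission and contacts with the endoplasmic reticulum were called in 28 of 39 cases, 11 higher and 17 lower, as they were adjusted over the list alone; camera did not call the set (adjusted p = 0.383). DNM1L, which encodes the fission GTPase DRP1, was 2.06-fold lower (log2 -1.04 ± 0.14, edgeR adjusted p = 0.000217), as was its receptor gene MFF (2-fold lower, 6.65e-05). MTFR2 was 3.89-fold and RMDN3 2.41-fold lower. ITPR3, a calcium channel gene, was 308-fold lower (75.1 ± 17.4 CPM, n = 2, against 0.247 ± 0.0824 CPM, n = 5). SPIRE1 was 331-fold and CHCHD6 3.37-fold higher. The fusion genes were not called: MFN2 differed by 0.21 ± 0.16 on the log2 scale (edgeR adjusted p = 0.277), MFN1 by -0.04 ± 0.15 (0.839) and OPA1 by -0.05 ± 0.18 (0.836). The signs of MFN1 and OPA1 turned on the FPKM scale, and that of MFN1 also with upper-quartile factors. Without parental replicate 3 MFN1 was at 0.15 and OPA1 at 0.04, and without MR1 replicate 4 OPA1 was at 0.04. Core autophagy genes were called in 25 of 44 cases (10 higher, 15 lower; 10 and 14 adjusted over the list alone), and lysosome genes in 45 of 63 (23 higher, 22 lower; 23 and 23 adjusted over the list alone). Camera called neither (adjusted p = 0.375 and 0.844), and the lysosome list had a positive median with a negative mean and test direction. By fry both lists were called (adjusted p = 0.0056 and 0.00499), among 26 of the 39 lists.

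**Figure D2:**
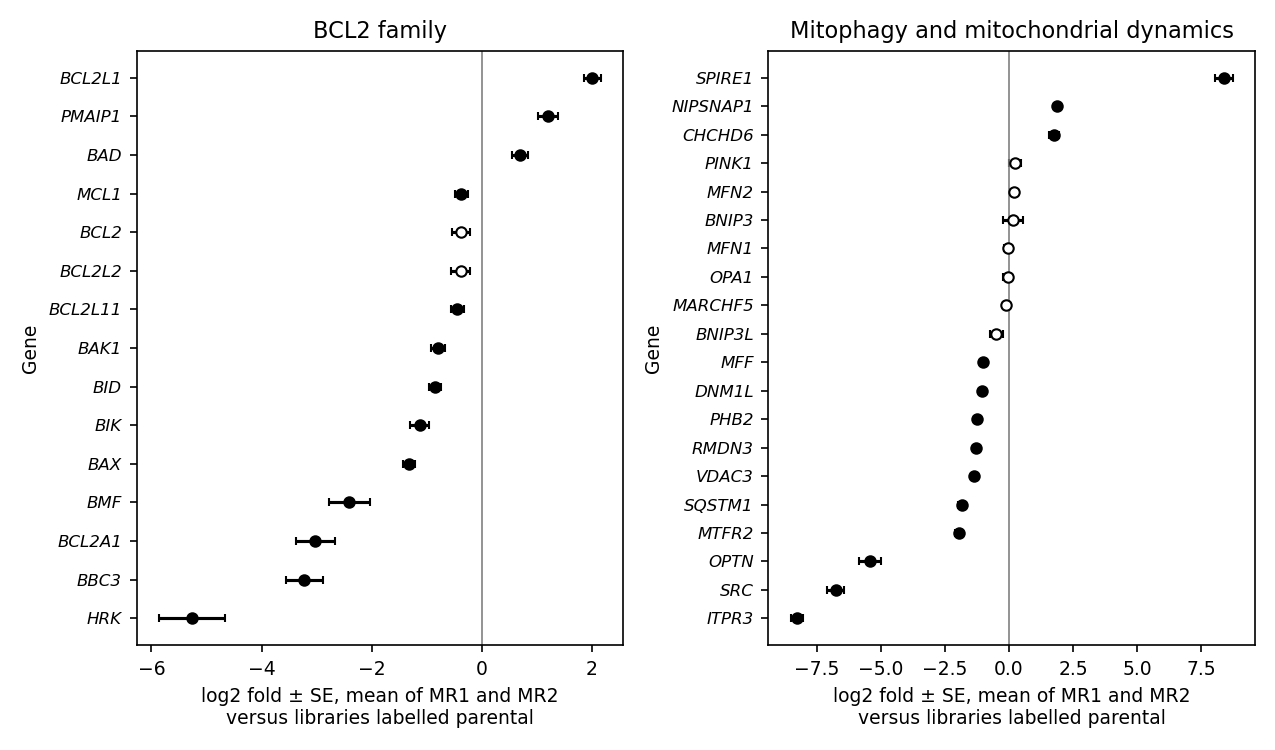
Log2 difference (x axis) with its standard error between the mean of MR1 and MR2 (n = 5 libraries) and the 2 libraries labelled parental for each gene (y axis) of the BCL2 family and of mitophagy and mitochondrial dynamics. Filled points passed an adjusted p of 0.05 by edgeR's quasi-likelihood test and open points did not; BOK, with no count in one arm, is left out. BCL2L1 is at 2.01 and MCL1 at -0.37, and PINK1, MFN1, MFN2, OPA1, BNIP3, BNIP3L and MARCHF5 are open.

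Camera with a preset correlation of 0.01 called 12 of the 39 gene lists with tested members, all toward lower levels in the resistant libraries. None of the 12 held with an estimated correlation. The camera adjusted p was then 0.845 for the replication and mitosis lists and 0.782 for the other 10. That test rests on the 4 residual degrees of freedom and called 0 lists in every contrast, so it had little power. MHC class I presentation, with an estimated correlation of only 0.08, was also at 0.782. A call lost by that test therefore does not show that correlation between genes made the call. The oxidative phosphorylation and mitosis calls also ended without MR2 replicate 2, and the stress response call without parental replicate 2. Mitochondrial protein genes were among them. Of 88 genes of the mitochondrial ribosome and import, 45 were lower and 6 higher (the same adjusted over the list alone; camera adjusted p = 0.000296), led by MRPL41 (5.67-fold lower), MRPL13 (3.75-fold), MRPL1 (4.54-fold) and MRPL44 (3.08-fold). Of 76 nuclear genes of oxidative phosphorylation, 31 were lower and 8 higher (28 and 7 adjusted over the list alone; camera adjusted p = 0.0334), with ATP5F1D 2.81-fold, CYC1 2.46-fold, COX6C 2.17-fold and NDUFA9 2.78-fold lower. Of 36 genes of the integrated and mitochondrial stress response, 20 were lower and 0 higher (the same adjusted over the list alone; 0.00484), among them TRIB3 (5.27-fold), HERPUD1 (3.65-fold), SHMT2 (2.41-fold) and CEBPG (2.66-fold).

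Growth-related lists were called in the same direction, with the same estimated-correlation limits. Of 44 genes of DNA replication, 21 were lower and 3 higher (camera adjusted p = 0.0137), with GINS4 5.04-fold, CDT1 3.86-fold, RFC3 2.78-fold and PCNA 2.32-fold lower. Of 47 mitosis genes, 19 were lower and 5 higher (0.028), with CDCA3 3.16-fold, CDC25C 2.69-fold, AURKB 2.58-fold and PTTG1 2.26-fold lower. Of 52 MYC target and ribosome biogenesis genes, 30 were lower and 2 higher (0.00484), with RRS1 2.72-fold, EXOSC5 2.67-fold, NCL 2.46-fold and NOP16 2.41-fold lower. In these 3 lists the counts were the same adjusted over the list alone, and 20, 23 and 20 genes were not called. Fry called the MYC list (adjusted p = 0.0251) but neither replication (0.101) nor mitosis (0.113). The proliferation genes MKI67 and TOP2A, named outside the rule, overlapped between the arms. MKI67 was at 498 and 598 CPM in the libraries labelled parental and 271 to 586 CPM in the resistant ones. TOP2A was at 523 and 619 CPM against 323 to 708 CPM. The list medians of the log2 difference were -0.46, -0.38 and -0.46. MR1 replicate 4 alone was lower than the mean of the other 4 resistant libraries in the same lists, by medians of -0.52, -0.50 and -0.26, with 0 of 44, 2 of 47 and 8 of 52 genes higher; without that library the 3 lists were still called. Of 29 p53 target genes, 16 were lower and 5 higher, as adjusted over the list alone (camera adjusted p = 0.028). CDKN1A, the gene of the cell cycle inhibitor p21, was 26.6-fold lower (181 ± 52.3 CPM, n = 2, against 6.71 ± 1.41 CPM, n = 5). BTG2 was 193-fold and RRM2B 6.38-fold lower. PHLDA3 had 3 counts in the resistant libraries together, a ratio of 1950 with a 95% counting interval of 665 to 9450.

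Immune and inflammatory lists were also called toward lower levels. Of 46 interferon-stimulated genes, 31 were lower and 5 higher (33 and 5 adjusted over the list alone; camera adjusted p = 0.000522). XAF1 was 11.2-fold lower, and BST2 (178-fold), TRIM22 (357-fold) and OAS1 (253-fold) were below 1 CPM in the resistant libraries. For MHC class I presentation 11 of 19 genes were lower and 1 higher, as adjusted over the list alone (0.00247). HLA-C was 12.2-fold and HLA-B 7.66-fold lower, values that are uncertain because these genes share reads with each other; PSMB10 was 4.13-fold and NLRC5 5.04-fold lower. In the NF-kB and inflammatory list 18 of 34 genes were lower and 6 higher (20 and 6 adjusted over the list alone; 0.0156). TNFAIP3 was 29.8-fold, LTB 293-fold and IER3 757-fold lower. TNFAIP2 had 2 counts in the resistant libraries together, both in MR1 replicate 6 (ratio 6260, counting interval 1730 to 51700). Of 32 immediate-early and AP-1 genes, 17 were lower and 4 higher, as adjusted over the list alone (0.028), with JUND 4.07-fold, ETV4 287-fold and SPRY4 237-fold lower. Of 26 monocyte and macrophage genes, 19 were lower and 2 higher (19 and 3 adjusted over the list alone; camera adjusted p = 0.000296). IRF8, a transcription factor gene of the monocyte lineage, was at 322 ± 26.5 CPM (n = 2) against 0.0886 ± 0.0759 CPM (n = 5). TYROBP was 591-fold and LILRB4 2350-fold lower, and MS4A6A had 3 counts in the resistant libraries together (ratio 4360, counting interval 1490 to 21200). The estimated-correlation adjusted p of 0.782 applies to each of these lists, and each direction is relative to libraries with 3 counts of RUNX1T1.

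The genes with the largest fitted changes were on in one arm and at or near 0 counts in the other. The 12 with the largest rise had no count in either library labelled parental. Against a floor of 3 counts over that group, MAGED1 was at least 3180-fold higher in the resistant libraries, at 125 ± 15 CPM (SD, n = 5). The nucleoside transporter gene SLC28A3 was at least 2270-fold, the guidance receptor gene ROBO1 at least 2260-fold, ZNF141 at least 1720-fold, the WNT co-receptor gene LRP6 at least 1420-fold and CELSR1 at least 1400-fold higher. CA8, ATP6V0E2, ZNF662, TCAM1P, TCEAL4 and ITM2A were at least 1180-fold to 1360-fold higher, of which TCAM1P is a pseudogene whose reads may be shared. At the other end, TEX15, CBR1, CSPG4 and MEIS1 had no count in any resistant library and were at least 6620-fold, 6460-fold, 6250-fold and 5160-fold lower. EIF4G3, PTPN3 and LITAF had 1 count in the resistant libraries together, with ratios of 39200 (95% counting interval 7030 to 1550000), 37200 (6670 to 1470000) and 32500 (5830 to 1280000). CES1 had 3 counts (ratio 16900, 5800 to 82200). PDLIM1 and GAS6 had 4 counts, CYP1B1 5 and LAMP5 10. In the libraries labelled parental they were at 287 ± 34.1, 177 ± 1.14, 250 ± 86.1 and 396 ± 54.5 CPM (SD, n = 2). All counts of CES1, PDLIM1 and CYP1B1 in resistant libraries lay in MR1 replicate 6, as did most of those of GAS6 and LAMP5. The single counts of EIF4G3, PTPN3 and LITAF lay in MR1 replicates 3, 6 and 4. Why many of these counts lay in 1 library was not tested.

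Taken line by line, MR1 and MR2 each differed from the libraries labelled parental at most tested genes. In MR1 10099 genes (57.5%) were called, 5197 higher and 4902 lower, and in MR2 9581 (54.6%), 5066 higher and 4515 lower. The highest genes by fitted change in both were MAGED1, ROBO1, SLC28A3, ZNF141, LRP6 and CELSR1, with MAGED1 at least 3170-fold higher in MR1 and at least 3200-fold higher in MR2. The lowest in MR1 were TEX15, CBR1, CSPG4, MEIS1, PHACTR3 and SNHG14. PHACTR3 was at least 2800-fold lower in MR1, and SNHG14, which overlaps other genes, had 1 count there (ratio 33500, counting interval 6010 to 1320000). The lowest in MR2 were LAMP5, PDLIM1, CYP1B1, CES1, GAS6 and EIF4G3, all at 0 counts in MR2, with LAMP5 at least 12800-fold and EIF4G3 at least 5020-fold lower. These differing names do not by themselves show a difference between the lines, and MR1 versus MR2 called no gene. The few counts that MR1 held of the genes lowest in MR2 lay mostly in MR1 replicate 6.

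MR1 and MR2 shared their calls. A total of 9226 genes were called in the same direction in both, 4825 higher and 4401 lower, and 0 in opposite directions. Independent lists of these sizes would share 1500 higher and 1261 lower genes. In 20 simulations all 7 libraries were drawn from common means, and both lines were set against the same 2 simulated control libraries. The largest number of shared calls was 0. With no gene changed hardly any call could arise, so that number is no measure for the 9226. The log2 changes of the lines correlated with r = 0.9921 across genes, against a simulated 0.569 ± 0.011 (SD), and their covariance was 10.83 against a simulated 0.0942 ± 0.003. The 2 control libraries could not be split with 2 left for each line, so part of the excess of shared calls over independent lists may come from sharing them. The simulated covariance holds only the random spread of the shared control libraries, and the difference from it was 10.73. An offset common to both control libraries, such as cells of another line, would enter both contrasts alike and was not simulated. The excess cannot tell changes that the lines share from such an offset. The shared calls rest on libraries that held 3 counts of RUNX1T1 each.

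**Figure D3:**
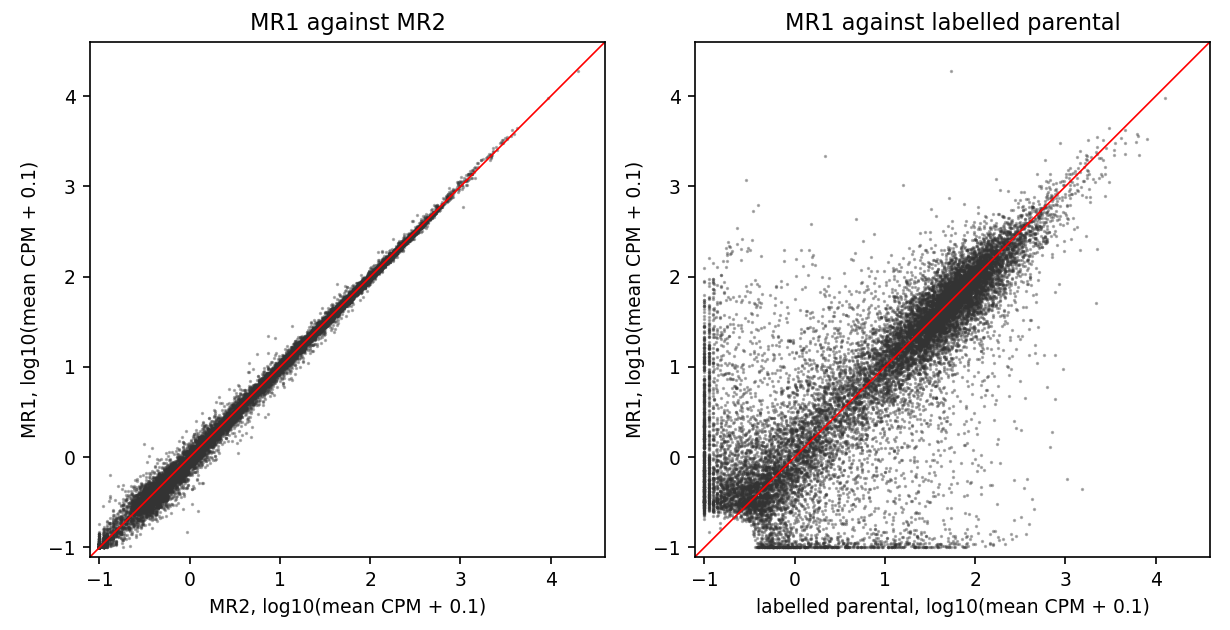
Mean TMM-scaled CPM plus 0.1 (log10 scale) of the 17550 tested genes, with 1 point per gene; MR1 (n = 3) is set against MR2 (n = 2) on the left and against the 2 libraries labelled parental on the right, and the red line marks equal values. MR1 and MR2 lie along the line, with 98.7% of genes of at least 10 CPM within 0.5 log2, and 45.8% of those genes lie as close between MR1 and the libraries labelled parental.

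MR1 and MR2, compared without the libraries labelled parental in the contrast, were close at most genes. By edgeR's quasi-likelihood test 0 of 17550 genes differed, and 139 had an unadjusted p under 0.05 against 878 expected by chance. DESeq2 also called 0. A count so far below expectation may come from a fitted spread too wide for this contrast, which was not tested. Genes are not independent, so the count can also lie far from expectation with a correct spread. The count does not measure how alike the lines are. For genes of at least 10 CPM, root mean square log2 differences between pairs of libraries were 0.196 to 0.425 across the lines. They were 0.252 to 0.538 within MR1 and 0.243 within MR2. The widest pair across the lines and the widest within MR1 both held MR1 replicate 4. Among 9479 genes of at least 10 CPM, 98.7% differed by less than 0.5 on the log2 scale, and the median standard error of these differences was 0.171. RUNX1T1, KIT, CD34 and MPO were at like levels in both lines: MPO, the myeloperoxidase gene, took 1.896% to 1.979% of all counts in MR1 and 2.022% and 2.094% in MR2. In simulated data of this design 31% of 2-fold and 72.6% of 4-fold changes were recovered. Most 2-fold and some 4-fold differences could therefore have been missed. Without a filter on low counts edgeR called 34 genes, 26 higher in MR1; in 22 of these 26 MR1 replicate 4 was the highest resistant library. On the FPKM scale without a filter limma called 33, all lower in MR1.

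By list, camera with the preset correlation called 9 of 39 lists higher in MR1 than in MR2, although no member of any list was called, or called adjusted over the list alone. The ribosomal protein list led (77 genes, median log2 difference 0.16, camera adjusted p = 4.85e-12), followed by hypoxia-induced genes (25 genes, median 0.28, or 0.25 with the gene at 0 counts set to its bound; 0.000824). None held with an estimated correlation (adjusted p = 0.845), a test of little power here, or by fry (adjusted p = 0.98). The calls moved with each resistant library: of the 9 lists, 1 was still called without MR1 replicate 4, 4 without MR2 replicate 2, 5 without MR1 replicate 3, 5 without MR2 replicate 5 and 6 without MR1 replicate 6. Ribosomal protein genes took 12.18% of counts in MR1 replicate 4 and 8.15% to 9.36% in the other 4 resistant libraries.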

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

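Leaving out MR1 replicate 4 was among the settings fixed before the data were seen, but attention was drawn to it after the data were seen. The 2 tests of that library, on depth and on admixture, were chosen after it was seen to stand apart, with their limits set before their results were seen.

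Between MR1 and MR2 camera called 9 gene lists, all higher in MR1, each drawing attention because it tests the difference between the lines itself. The adjusted p was 4.85e-12 for cytosolic ribosomal proteins, 0.000824 for hypoxia-induced genes, 0.00503 for the NF-kB and inflammatory list, 0.00871 for T and NK cell genes, 0.00987 for oxidative phosphorylation, 0.0253 for mitophagy and for the mitochondrial ribosome and import, 0.0258 for immediate-early and AP-1 genes and 0.0317 for glycolysis. No gene of these lists was called between the lines by edgeR, and 0 lists held with an estimated correlation or by fry. Leaving out MR1 replicate 4, 8 lists were called, all higher in MR1, of which only the mitochondrial ribosome and import list (adjusted p = 0.00878) was among the 9. The hypoxia-induced (0.747) and NF-kB (0.654) lists then pointed the other way, uncalled, and DNA replication (7.82e-05) and mitosis (0.000178) were called. MR1 had 3 libraries with this one and 2 without it. The calls were unstable to the other resistant libraries as well: 4 of the 9 stayed without MR2 replicate 2, 5 without MR1 replicate 3, 5 without MR2 replicate 5 and 6 without MR1 replicate 6.

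MR1 replicate 4 stood apart from the other 4 resistant libraries, at a median distance of 0.438 (root mean square of log2 CPM differences over genes of at least 10 CPM), where the largest distance among the other 4 was 0.314. It was also the deepest library, but after thinning to the smallest total its median distance was 0.439 against 0.311, so depth does not account for it. Cells like those in the libraries labelled parental do not account for it either: over 63 genes above 50 CPM in those libraries and under 0.5 CPM in the other 4 resistant ones, its median share of the parental level was 0.0221%. A difference in the state of that culture remains open and may underlie part of the list calls between the lines; the labels record nothing of it and it was not tested.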

How the results depend on the processing

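Thinning and removal of the length trend were chosen after seeing the data. The counts against the libraries labelled parental stayed within 1.5 times of the main ones in every alternative run. Leaving out 1 library gave 7834 to 11127 genes in MR1, 7383 to 11154 in MR2, 8251 to 11809 in the mean of both lines and 7180 to 10224 shared in direction; where a group was left with 1 library, it was assumed to vary like the others. Both libraries labelled parental are in doubt and cannot both be left out of a comparison with parental. A replicate block on the 4 libraries with a shared number gave 10992 genes in the mean contrast, against 10496 for the same libraries without the block; each number is shared by 1 library per arm and 1 residual degree of freedom was left. Scaling moved the median log2 difference of the mean contrast from 0.066 (TMM) to 0.029 (RLE) or 0.106 (upper quartile), and the share of higher calls from 51.6% to 49.8% or 53.5%. For MR1 versus MR2 the count was 0 in all alternatives but those without a filter on low counts, where edgeR called 34 and limma on FPKM 33. Without the filter edgeR's prior degrees of freedom were infinite, against 4.71, so each gene's own spread was no longer used, and 31 of the 34 genes were also tested with the filter; the cause of the 33 was not tested. Of the lists in the mean contrast, 12 became 0 with an estimated correlation, a test of little power here. By fry 26 were called, 10 of them among the 12 (DNA replication and mitosis were not). Fry asks another question. The number was 10 to 13 when 1 library was left out. Oxidative phosphorylation and mitosis were lost without MR2 replicate 2, and the integrated and mitochondrial stress response without parental replicate 2, where cholesterol biosynthesis was gained. MHC class II was gained without MR1 replicate 4. On ranks the same 12 were called. Between MR1 and MR2, 9 lists became 0 with an estimated correlation and 0 by fry, 12 on ranks with all 9 among them, and 5 to 10 when 1 library was left out. The lists also changed: of the 9, 5 stayed among 5 called without MR1 replicate 3, 1 among 8 without MR1 replicate 4, 6 among 10 without MR1 replicate 6, 4 among 9 without MR2 replicate 2 and 5 among 7 without MR2 replicate 5. The cause was not tested. Most named genes were picked for large changes or small adjusted p in these same data, which favours keeping their calls. Among values of named genes under alternatives, 2561 kept direction and side of the threshold, 11 lost and 10 gained a call, and 12 turned sign. The latter were all uncalled: MFN1 at 0.0013 with upper-quartile factors, MFN1 at 0.066 and OPA1 at 0.036 by limma on log2(FPKM + 0.1) with or without a filter, 0.055 and 0.035 on log2(FPKM + 1), and when 1 library was left out MFN1 -0.21 to 0.15, OPA1 -0.13 to 0.043 and BNIP3 -0.23 to 0.67; the cause was not tested. Depth limits what can be said of genes at 0 to 3 counts in an arm, where only bounds or counting intervals are given.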

Other observations

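The tests in the last paragraph of this part, of why the libraries labelled parental stood apart, were chosen after those libraries were seen to differ. The limits that would decide each of them were set before its result was seen. The gene lists and their tests were fixed before the data were examined. Genes named in the next 3 paragraphs were chosen after their values were seen.

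Lineage genes not described above also differed between the resistant libraries and the libraries labelled parental, and camera called none of these lists. Fry called each of them but the granulocytic list (adjusted p = 0.265). Of 31 stem and progenitor genes 15 were higher and 10 lower in the resistant libraries; ERG was at 130 CPM against 0.0378 CPM, and FLT3 at 16.7 CPM against 457 CPM. Of 26 granulocytic genes 9 were higher and 14 lower: MPO was at 19560 CPM against 53.8 CPM, while ELANE was at 12.2 CPM against 767 CPM and CEBPA at 25.6 CPM against 496 CPM. Of 14 megakaryocyte and platelet genes 10 were higher and 3 lower, with SPARC at 617 CPM against 0.294 CPM. Erythroid genes were 7 higher and 1 lower of 11, mast cell and eosinophil genes 10 and 4 of 15, B-lineage genes 6 and 3 of 11, and T and NK cell genes 8 and 9 of 17. Of 10 MHC class II genes 5 were lower and 5 not called, with CD74 at 0.543 CPM against 374 CPM. In all these lists the counts were the same adjusted over the list alone. Stromal and epithelial genes were 4 higher and 7 lower of 12 (4 and 8 adjusted over the list alone), with PDGFRA at 1167 CPM against 0.189 CPM.

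Other fixed lists went both ways and were not called by camera. By fry the drug transporter, caspase, receptor tyrosine kinase and NRF2 lists were called (adjusted p = 0.00125, 0.000173, 0.00449 and 0.0271). Drug transporter genes were 5 higher and 4 lower of 15; ABCB1, the P-glycoprotein gene, was at 17.3 CPM against 0.0119 CPM, and ABCC1 at 360 CPM against 49.9 CPM. Caspase and apoptosome genes were 4 higher and 12 lower of 28, with APAF1 at 46.2 CPM against 162 CPM. Regulators of MCL1 turnover and translation were 6 and 5 of 23, signalling genes of receptor tyrosine kinases, RAS and PI3K 18 and 18 of 56, adhesion genes 14 and 15 of 33, hypoxia-induced genes 12 and 6 of 25, cholesterol genes 2 and 7 of 24 and fatty acid oxidation genes 7 and 13 of 30, with the same counts adjusted over the list alone. Glycolysis genes were 8 and 5 of 27 (7 and 5 adjusted over the list alone), NRF2 and glutathione genes 11 and 13 of 35 (11 and 15), ribosomal protein genes 6 and 22 of 77 (5 and 19) and replication-dependent histone genes 1 and 3 of 11 (0 and 3). Median, mean and test differed in sign for ribosomal proteins, fatty acid oxidation, adhesion and receptor tyrosine kinase genes. Each of these directions is relative to libraries with 3 counts of RUNX1T1.

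MR1 replicate 4 is given here as values of 1 library against the mean of the other 4 resistant ones, without a test. Of 25 hypoxia-induced genes 23 were higher there, with a median log2 difference of 0.94. The hypoxia-induced gene NDRG1 was at 162 CPM against 22.5 to 63.2 CPM in the other 4, PFKFB4 at 456 CPM against 141 to 185 CPM and VEGFA at 272 CPM against 123 to 162 CPM. Ribosomal protein genes were higher in 76 of 77 cases (median 0.42). DNA replication genes were higher in 0 of 44 cases (median -0.52), and mitosis genes in 2 of 47 (median -0.50). The proliferation gene MKI67 was at 271 CPM against 468 to 586 CPM.

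The libraries labelled parental stood far from all resistant libraries, with 60.6% of genes called. Parental replicate 3 had the smallest total, 38147759, just below the resistant range, which alone would leave a depth effect open. It is argued against by thinning all libraries to that total, after which 10419 genes were called, and a gene length bias by the 10205 of the 10636 calls that stayed once a smooth length trend was removed. That the resistant libraries are not the RUNX1-RUNX1T1 line is argued against by RUNX1T1 of at least 118.3 CPM in each of them. The highest RUNX1T1 level in the libraries labelled parental was 0.0786 CPM, and POU4F1 was at 1.39 and 0.996 CPM there. Pearson's r with resistant libraries was 0.3985 to 0.4214, against 0.9596 to 0.9921 within groups. These values argue against these 2 libraries holding the cells that gave MR1 and MR2. A wrong label or another culture would give such values. Expression alone does not name the line they hold, and the reads were not genotyped or searched for the fusion. Resistance gained by cells of the fusion line would start from libraries that hold RUNX1T1, so the RUNX1T1 value argues against resistance as the whole cause. That part of the differences came with resistance stays open as untested, because it would sit in the same contrast; if the label is wrong, the differences from parental would not describe resistance.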
